A study of Mus musculus with 2 samples.

How the data were processed

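Gene expression in mouse liver lacking the membrane-anchored metalloproteinase MMP-14 was compared with wild type on 2 oligonucleotide arrays read in 2 colours, 1 array per comparison. The first array carried RNA of Dlk-positive cells sorted from fetal liver, labelled embryonic day 14 in the sample labels and 14.5 in the design text, with RNA from 100000 cells and 3 livers per genotype. The second carried RNA of whole liver, for which the labels say postnatal day 1 and the design text says embryonic day 18.5, mixed from 2 livers per genotype. This conflict was not settled, and the second array is called the P1 liver array after its label. On both arrays the wild type was labelled with Cy5 and the knockout with Cy3, per the labels, and no array had the dyes swapped. There is therefore no replicate array, no test and no p-value, and a gene-specific effect of the dye cannot be told apart from genotype. The number of arrays limits the precision of every value.

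RNA was amplified and coupled to dye with an amino allyl kit, following a protocol of the array maker, per the labels' protocols. The deposited scanner files hold spot intensities of both channels with a local background for each spot, per the file headers, and these intensities were not normalised. Each array had 27456 spots, of which 2736 were blank spots, and 23473 gene probes. The deposited value table of the authors holds log2 ratios of knockout over wild type. Set against the scanner values, these log2 values of the authors equalled the ratio of the channels after subtraction of the trimmed blank mean, centred on the array median, with a correlation of 1 across probes to the digits written. The column medians were 7.21e-07 on the first array and -2.74e-05 on the second, so scale, centring and direction are all known. A value was present where both channels exceeded the blank threshold, except for 1 probe on the first array and 7 on the second.

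The main values were made with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, the log2 ratios were normalised within each array by loess with control spots at weight 0, spots of a probe were averaged, and probes of a gene were averaged. Normexp was run on the spot signal without the local background columns. This was decided after the files were seen, because the local background followed the spot (Spearman correlation 0.921 and 0.967 for the wild-type and knockout channels of the first array, and 0.900 and 0.948 for the second). At the positive controls of the first array the local background of the knockout channel had a median of 5626, against 73.6 at blank spots. Normexp with the local background was run as an added alternative. The offset of 50 shrinks the ratios of dim genes, so the authors' deposited value is given beside key genes and named as such.

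A channel was called detectable above the blank mean plus 2 SD, after 5 percent of the blank spots was removed at each end. On the E14 Dlk+ array 17336 probes were detectable in both channels, and on the P1 liver array 17342. Median probe signals were 58.5 in the wild-type and 122 in the knockout channel of the first array, against thresholds of 44.3 and 85.1. On the second array they were 73.4 and 113, against 50.5 and 87.0. The 4 quality-flagged probes of the first array were left out.

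Of the 23473 probes, 16631 had 1 gene symbol in the platform annotation, none had several, and 6842 were unnamed here. Symbols were updated with a RefSeq gene table of assembly GRCm38.p6. There, 12622 symbols were current, 3947 were updated from an older symbol and 62 were kept as given. The files name no genome build, so no coordinates are given and that table served only for names and for which genes neighbour each other. A total of 229 genes had several probes. Among the 139 of them detectable in both channels by several probes, the SD between probes of a gene was 0.12 on the E14 Dlk+ array and 0.22 on the P1 liver array, and 5 genes of the second had probes on both sides of the 2-fold threshold.

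Genes were counted at a fixed size of 2-fold among genes detectable in both channels. Before the data were examined, 35 gene lists were fixed. For each list with at least 5 members detectable in at least 1 channel, the median log2 ratio was placed among 10000 random lists of the same size matched on mean log2 intensity in 20 bins, as a description of that array. The Y-linked list had 1 measured member on each array, too few for a median. Named genes were the 12 highest and 12 lowest of each array at or above the 25th percentile of intensity, up to 4 members of each list, 12 genes fixed by name, and the 6 genes with the largest shared and the 6 with the largest opposite change over both arrays. A further 11 lists, of lung, liver stroma and other organs, were written after the largest changes had been seen. A bound is given for a gene detectable in 1 channel only, from channel values after loess and Aquantile normalisation, and is open to dye bias.

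The scripts were tested on simulated data. Over 23470 spots of the first array and 23474 of the second, on arrays simulated from the spots of each real array with 200 changed spots, the direction was right for 57 of 57 detectable spots changed 2-fold on the E14 Dlk+ array and for 62 of 62 on the P1 liver array, while the median size recovered was 0.48 and 0.58 on the log2 scale. Only 1 of the 57 and 5 of the 62 passed the 2-fold threshold, so most true 2-fold changes are missed by the counts at that threshold. Of spots changed 4-fold, 41 of 68 and 32 of 56 passed it, and of unchanged spots 0 of 16941 and 0 of 17212 did. The noise put into the simulation was small, with a median size of 0.04 on the log2 scale for unchanged spots of either array. It held no effect of dye, ceiling or animals. The count of 0 follows from that setting and gives no rate of false calls for the real arrays. Of 200 random lists of 20 genes, drawn from 13975 and 13847 genes, 5.5 percent on the first array and 3 percent on the second lay outside the central 95 percent, and all lists shifted by 0.3 on the log2 scale were found. This checks the ranking only, since lists of genes that vary together were not simulated. The shift of 0.3 exceeds every E14 median of the lists fixed beforehand, of which the largest in size was 0.26. Detection of smaller shifts was not tested.

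The alternatives planned were plain subtraction of the local background, no background correction, a normexp offset of 10, median centring in place of loess, the authors' values, no filter on dim genes, only genes of at least median intensity, the brightest probe of each gene, thresholds of 1.5-fold and 3-fold, the mean of list members, and only list members detectable in both channels. Alternatives added after seeing the data were normexp with the local background, subtraction of the blank mean followed by loess, leaving out genes read as whole numbers (a deposited intensity exactly equal to a whole number in either channel, with no tolerance and no level of brightness set), and leaving out the genes of the lung lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.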

Results

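Expression was measured on 2 arrays, each setting MMP-14 knockout liver RNA against wild-type RNA. MMP-14 is a membrane-anchored metalloproteinase that cleaves matrix proteins and activates MMP-2. The first array compared Dlk-positive fetal liver cells, a population rich in hepatoblasts, and the second compared whole liver labelled P1. There was 1 array per comparison, so no value has an error between animals, and all ratios are log2 of knockout over wild type. Of the named genes, 12705 were detectable in both channels on the E14 Dlk+ array and 12715 on the P1 liver array.

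The targeted gene was lower in the knockout on both arrays. Mmp14 had a log2 ratio of -1.13 on the E14 Dlk+ array and -1.30 on the P1 liver array. In the authors' deposited table it stood at -2.13 and -2.83, and with the local background used in normexp at -0.45 and -0.27. The part of the gene its probe covers relative to the deletion is not given in the sources used here. Its signal was dim, at 131 in the wild-type and 132 in the knockout channel of the first array, where knockout readings exceeded wild-type readings by a median factor of 2.19. On the P1 array the signals of Mmp14 were 161 and 104, against detection thresholds of 50.5 and 87.0. Lung genes were higher in the wild-type P1 channel, as described below. Whether that adds to the P1 ratio of Mmp14 was not tested.

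In the sorted E14 cells, genes of stellate cells and fibroblasts were higher in the knockout. With 1 array of sorted cells, a change of expression within a cell type cannot be told apart from a different mix of cells after sorting. The list of stellate, fibroblast and smooth muscle markers had a median of 0.26, at the 100th percentile of matched random lists, with 27 of 30 members above 0 and 5 at least 1.5-fold higher, among them the proteoglycan gene Dcn (0.86), the stellate cell transcription factor gene Lhx2 (0.80) and Tagln (0.68). Outside this list, Colec10 (1.09) and Colec11 (0.91), which encode collectins, and the insulin-like growth factor binding protein genes Igfbp3 (0.98) and Igfbp7 (0.93) were among the 12 highest genes. The extracellular matrix list had a median of 0.08 (99.97th percentile), with 7 of 44 members at least 1.5-fold higher, among them Lum (0.66), Col4a2 (0.65) and Postn (0.62). Mesothelial markers were lower, with a median of -0.14 (below all random lists), 3 of 16 members above 0, Upk3b at -1.01 and Podxl at -0.64.

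Several other lists lay outside the central 95 percent of random lists on the E14 array. Immediate early and dissociation stress genes, a quality list, had a median of 0.17, with Hspb1 at 0.58 and Dusp1 at 0.52. The medians were 0.10 for cell cycle genes, 0.08 for YAP targets, 0.05 for neutrophil markers (0.63 in the authors' values) and 0.05 for megakaryocyte markers, which lay at the 66.0th percentile in the authors' values. The neutrophil genes with the largest ratios were dim, with wild-type signals from 51.6 (Prtn3) to 64.8 (S100a8) against a threshold of 44.3. The neutrophil median of 0.63 rests on 14 members and that of 0.05 on 19. Sterol and lipid synthesis had a median of -0.11 and the unfolded protein and amino acid stress list -0.07, with Mthfd2 at -0.53 and Psat1 at -0.46, and each of the 2 lists had 6 of 25 members above 0. Under median centring in place of loess, the medians of sterol synthesis (0.50) and unfolded protein genes (0.54) turned positive, and those of megakaryocyte (-0.14) and neutrophil markers (-0.025) negative, while the median of all genes was 0.29. Among matched random lists under that setting, sterol synthesis stayed at the 0.01st, unfolded protein genes at the 1.32nd and neutrophil markers at the 99.93rd percentile, and megakaryocyte markers lay at the 95.9th. The sterol synthesis list lay within the random range with the local background subtracted (0.0039, 72.1st percentile) and with it used in normexp (0.031, 51.5th percentile).

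Hepatocyte, hepatoblast and bile duct lists lay within the central 95 percent of random lists on the E14 array in the main values. The hepatocyte maturation list had a median of -0.03 (3.42nd percentile), the hepatoblast list -0.02 (13.5th percentile) and the bile duct list -0.03 (3.01st percentile; 2.28th in the authors' values). Of the 22 hepatoblast members, 10 were above 0 and 0 were at least 1.5-fold higher. At least 1.5-fold lower were 4: Afp (-1.26), Igf2 (-0.70), H19 (-0.70) and Ahsg (-0.69). All 4 were bright, and Afp and H19 were read as whole numbers. Dlk1 stood at -0.03, Sox9 at 0.08, Spp1 at -0.04 and Krt19 at -0.01. The signals of Krt19, 46.3 and 93.1, lay near the thresholds of 44.3 and 85.1, so its ratio says little. Egfr, the receptor of epidermal growth factor, had a ratio of 0.59, and 1.10 in the authors' deposited table. The Notch list had a median of 0.01, with Hes1 at 0.38 and Notch1 at 0.35.

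In total, 2 genes were at least 2-fold higher and 12 at least 2-fold lower in the knockout on the E14 array. In the authors' values the split was 160 higher and 34 lower, and with median centring 155 higher and 1 lower, so the balance of directions depends on the scaling. The higher genes were Supt16 (1.26), a subunit of a histone chaperone, and Colec10. Of the 12 lower genes, 10 had a whole-number reading in at least 1 channel, a kind of reading seen only at the top of the range. They were Mt2 (-2.01), Trf (-1.39), Mt1 (-1.38), Ttr (-1.36), Alb (-1.31), Afp (-1.26), Serpina6 (-1.18) and Apoa2 (-1.05), with Rpl41 (-1.34) and Ppia (-1.04), which are expressed in most cells. Whole-number readings started at 28390 in the wild-type and 32697 in the knockout channel, and 3 knockout readings above that were not whole. Without genes read as whole numbers, 2 were at least 2-fold lower, Mmp14 and Upk3b.

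**Figure D1:**
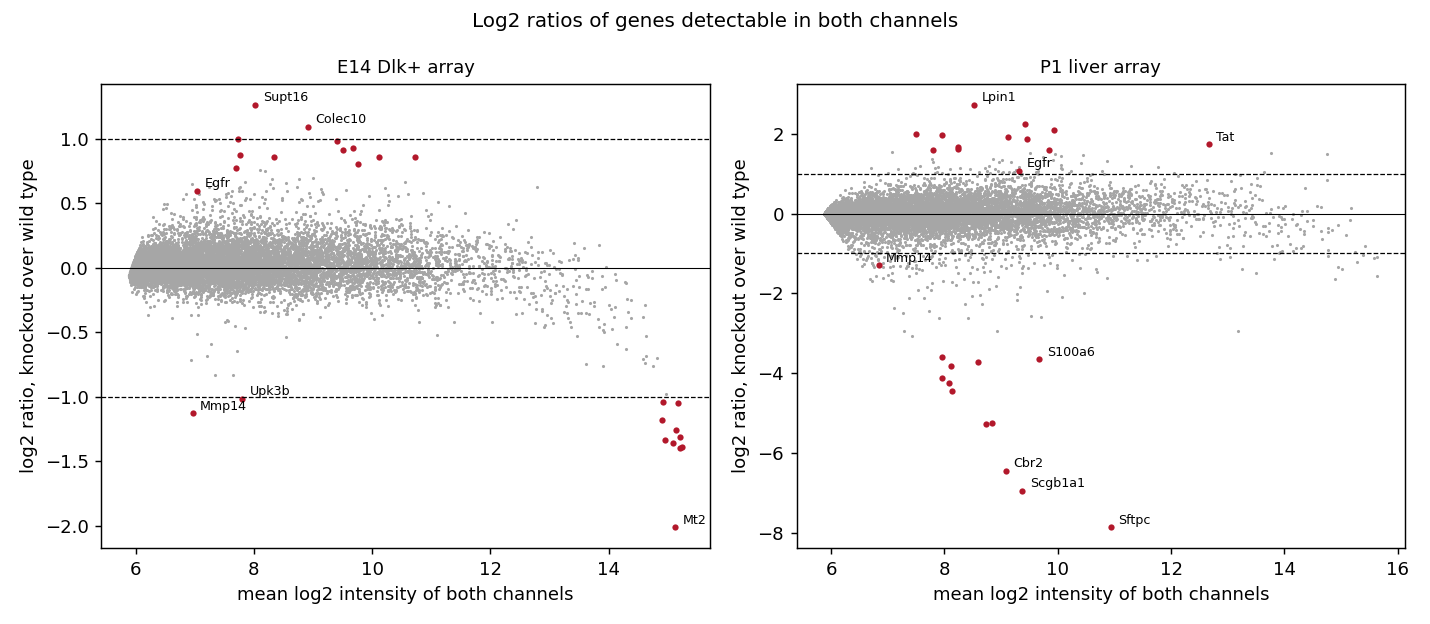
Each point is a gene detectable in both channels, with its mean log2 intensity on the x axis and its log2 ratio of knockout over wild type on the y axis, for the E14 Dlk+ array (left) and the P1 liver array (right, wider y scale). Red points are the 12 highest and 12 lowest genes of each array with Mmp14 and Egfr, and dashed lines mark 2-fold; on the left the brightest genes bend downwards, and on the right Sftpc reaches -7.85.

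In whole liver labelled P1, genes of lung epithelium had the lowest ratios, with more signal in the wild-type channel. Sftpc, which encodes surfactant protein C, had a ratio of -7.85, with a signal of 24038 in the wild-type and 187 in the knockout channel. Scgb1a1 (-6.95), a club cell secretoglobin, Cbr2 (-6.44), Sftpa1 (-5.26), Slc34a2 (-5.24), Sftpd (-4.43) and Ager (-4.24) followed. On the E14 array Sftpc was detectable in 1 channel only, near the threshold, with signals of 41.8 and 85.2. Cxcl15 and Scgb3a2, chosen after their values were seen, were detectable in the wild-type P1 channel only and were at least 19.9-fold and 18.9-fold lower in the knockout.

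**Figure D2:**
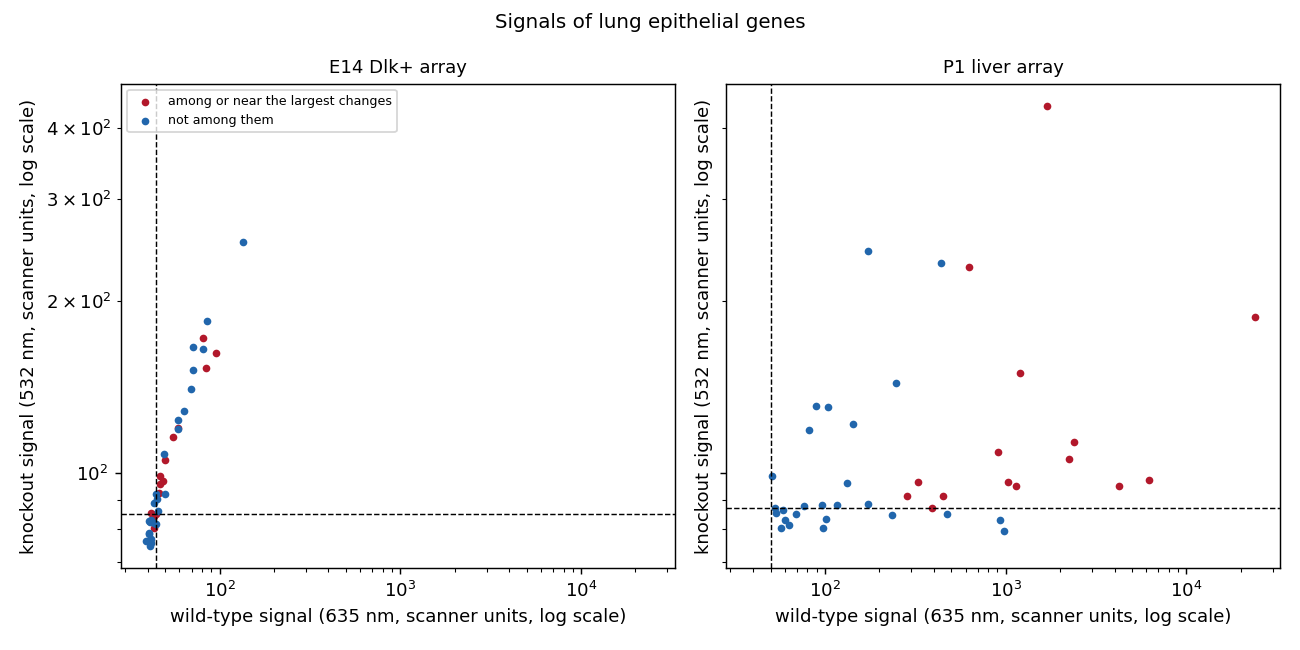
Each point is a lung epithelial gene, with its wild-type signal on the x axis and its knockout signal on the y axis, both in scanner units on log scales; dashed lines mark the detection threshold of each channel. Genes lie along a single diagonal on the E14 Dlk+ array (left), whereas on the P1 liver array (right) wild-type signals reach 24038 while the knockout signal of that gene is 187.

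Matrix, vessel and stromal genes were lower in the P1 knockout, beside these lung genes. The extracellular matrix list had a median of -0.52, with 10 of 44 members at least 2-fold lower, among them Col6a1 (-2.61), Col3a1 (-1.93) and Col4a2 (-1.85). Endothelial markers had a median of -0.50, with 2 of 28 members above 0 and Egfl7 at -1.54, and stellate and fibroblast markers -0.38, with 4 of 30 members above 0, Mfap4 at -4.12 and Acta2 at -2.11. All 3 medians lay below every random list. Of the genes named here, Col6a1, Egfl7 and Mfap4 are also in the lung lists written after the largest changes were seen. With the genes of the lung lists left out, the medians were -0.35 for matrix, -0.37 for endothelial and -0.14 for stellate and fibroblast markers. Some of the genes left out were picked after their low values were seen, which by itself raises these medians. The genes left in were not checked for expression in lung, so these medians do not separate liver stroma from lung. The TGF-beta list (-0.32), metalloproteinases (-0.15), integrins (-0.14), ERK response genes (-0.17), YAP targets (-0.23) and the Notch list (-0.19) were lower as well. The 3 ERK response genes at least 2-fold lower, Egr1, Fos and Ier3, are also in the immediate early list below. Mmp2, the protease that MMP-14 activates, had a ratio of -1.08, against 0.09 on the E14 array. On the P1 array Mmp2 was lower beside the stromal and lung genes above, and a link to the loss of MMP-14 was not tested.

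Erythroid, macrophage and immediate early genes were also lower in the P1 knockout. Whether the lung signal of the wild-type channel adds to these ratios was not tested. Leaving out the genes of the lung lists took no member from these lists, so it does not bear on this. Erythroid markers had a median of -0.57, with 1 of 23 members above 0 and 6 at least 2-fold lower, among them Car2 (-1.16), Rhd (-1.15) and Klf1 (-1.10). Macrophage markers had a median of -0.26 and cell cycle genes -0.22. Under median centring these 2 medians were 0.014 and 0.026, still at the 0.51st and 0.08th percentile of random lists. Neutrophil markers (-0.12, 3.17th percentile; 2.46th in the authors' values) and megakaryocyte markers (0.03, 65.9th percentile) lay within the random range in the main values. Immediate early and dissociation stress genes had a median of -0.49, with Fos at -1.30 and Klf4 at -1.19. The acute phase list had a median of -0.22, and of -0.14 (0.80th percentile) without genes read as whole numbers, and the growth hormone and IGF list -0.19, which was 0.017 with the local background used in normexp. The unfolded protein list lay at the edge (-0.13, 2.75th percentile, and 0.46th in the authors' values), with Hsp90b1 at -1.49 and Hspa5 at -1.38.

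Genes of sterol synthesis were higher in the P1 knockout. Lpin1, a phosphatidate phosphatase, had the highest ratio among the ranked genes at 2.73, followed by the sterol synthesis gene Msmo1 (2.25) and Retreg1 (2.10). The sterol and lipid synthesis list had a median of 0.45, above all random lists, with Idi1 at 1.59 and Cyp51 at 1.29. Of its 24 members, 16 were above 0 and 8 below, with 9 at least 1.5-fold higher and 1 at least 1.5-fold lower. The glucocorticoid and clock list had a median of 0.17 (99.95th percentile in the main values, but 95.3rd in the authors' values, and outside the random range in 11 of 14 alternatives), with Tat, a tyrosine-degrading enzyme, at 1.73 and the metallothionein gene Mt2 at 1.51. Ppargc1a, a coactivator of fasting metabolism, stood at 1.67 and Pck1 at 0.89. The hepatocyte maturation list had a median of 0.15 (95.9th percentile, 99th in the authors' values and 99.8th without genes read as whole numbers), with Tdo2 at 1.86. Members of that list went both ways, and Alb (-1.12) and Ttr (-1.65) were read at the top of the range.

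The EGF receptor list had a median of 0.08 (96.1st percentile) on the P1 array. Egfr stood at 1.07, and at 1.30 in the authors' deposited table, and its inhibitor Errfi1 at 1.02. The bile duct list had a median of -0.08 (5.80th percentile, 0.94th in the authors' values and 13.2nd without the genes of the lung lists). Of its 22 members, 4 were at least 2-fold lower and 0 at least 2-fold higher. The lower ones were Muc1 (-2.37), which is also in a lung list, Aqp1 (-1.36), Epcam (-1.23) and Cd24a (-1.03). Leaving out the lung lists left 21 members, and these were not checked for expression in lung. Sox9 stood at 0.17 and Spp1 at -0.13, and Krt19 was not detectable in either channel.

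On the P1 array 71 genes were at least 2-fold higher and 185 at least 2-fold lower in the knockout. The authors' values gave 403 and 641, and median centring 274 and 117. Without the genes of the lung lists 150 genes were lower. Outside the central 95 percent of random lists lay 17 lists on the P1 array and 10 on the E14 array, of 34 examined on each. Some lists share genes, so these counts are not of independent results.

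**Figure D3:**
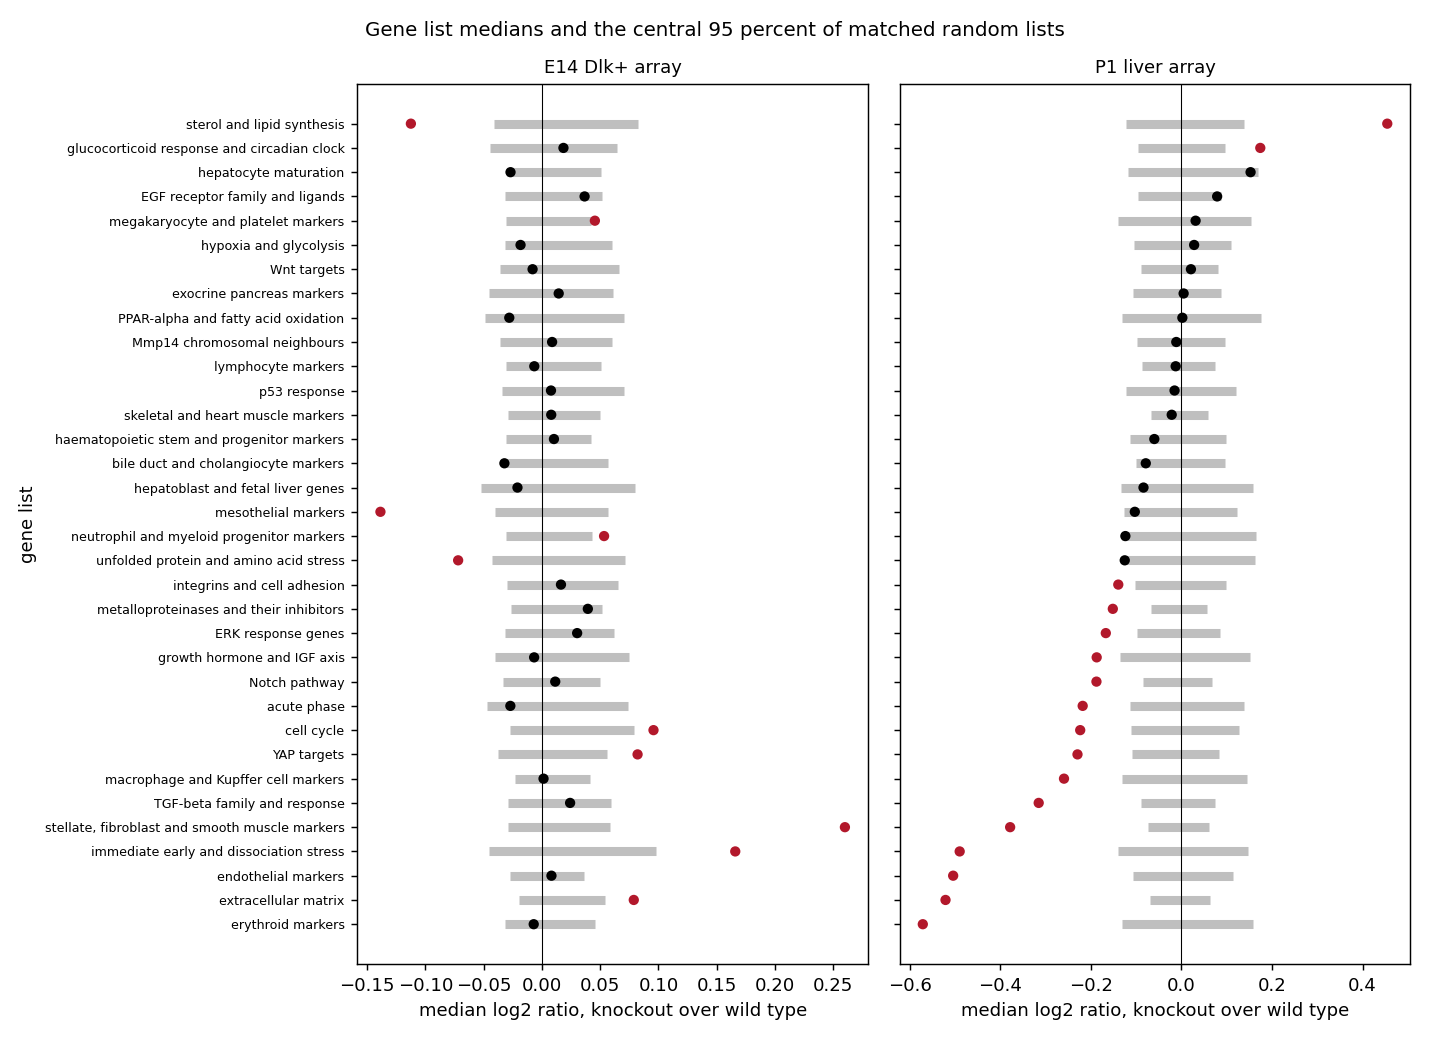
Points give the median log2 ratio of each gene list (x axis) on the E14 Dlk+ array (left) and the P1 liver array (right, wider x scale), and grey bars the central 95 percent of random lists matched on intensity. Red points lie outside the bar; the stellate list stands at 0.26 on the left and -0.38 on the right.

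Across 12005 genes detectable on both arrays, the log2 ratios correlated with a Pearson coefficient of 0.084 and a Spearman coefficient of 0.157. The Pearson coefficient was 0.377 under median centring and 0.410 with the local background used in normexp. Genes are not independent replicates, and the knockout was in the same dye on both arrays. In the main values 5 genes were at least 2-fold changed the same way on both. The count was 11 in the authors' values, 24 under median centring, 82 with the local background used in normexp and 265 with it subtracted. Supt16 was higher on both (1.26 and 1.36), where independent lists would share 0.0108 genes. Alb, Mmp14, Trf and Ttr were lower on both, against 0.175 for independent lists, and 3 of these 4 were read at the top of the range. In the authors' values 5 genes were higher on both, against 3.20 for independent lists, and 6 were lower, against 1.24.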

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

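All tests of the ceiling, of dilution and of Supt16 were chosen after the results were seen, while those of lung RNA, other organs and lung stroma were written before their results. The requirement that the lung stroma, ceiling and flanking segment tests meet a bound on 2 scales was set after main values had been seen. The 2 arrays have no replicates, so none of the differences between them was tested.

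On 6 gene lists the arrays lay outside the central 95 percent of random lists in opposite directions. The P1 median minus the E14 median was -0.60 for extracellular matrix (0.08 and -0.52 on the E14 and P1 arrays), -0.64 for stellate, fibroblast and smooth muscle markers (0.26 and -0.38) and -0.66 for immediate early genes (0.17 and -0.49). It was -0.32 for cell cycle genes (0.10 and -0.22), -0.31 for YAP targets (0.08 and -0.23) and 0.57 for sterol and lipid synthesis (-0.11 and 0.45), whose E14 median lay within the random range wherever the local background was used. The 6 genes with the largest opposite changes gave differences of 3.52 for Mt2 and 2.88 for Mt1, both read at the top of the range on the E14 array and Mt1 on the P1 array too, and -3.43 for Fhl1, -1.79 for Igfbp7, -1.75 for Crip2 and -1.52 for Adamts1. The P1 ratio of Igfbp7 turned positive wherever the local background was subtracted. Fhl1 is also in a lung list. Without the genes of the lung lists, the P1 medians were -0.35 for extracellular matrix and -0.14 for stellate, fibroblast and smooth muscle markers. The first array carried sorted Dlk-positive cells and the second whole liver, so these differences cannot be ascribed to stage.

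The first pattern is the set of lung genes in the wild-type P1 channel. Lung epithelial genes written down without having been seen among the largest changes had a median of -1.76 in the authors' values, below all random lists (central 95 percent from -0.36 to 0.21), and -0.69 in the main values, and all 26 on the array were detectable in the wild-type channel against 14 in the knockout channel and 15 in the wild-type channel of the E14 array. This is in line with lung RNA in the wild-type P1 pool, and argues less for other organs, since the lowest percentile among the 2 lists with enough members was 6.25, for kidney. Whether lung stroma is the whole cause of the lower vessel, stellate and matrix lists stays open: liver sinusoidal and stellate genes had a pooled median of -0.0701 in the main values (7.19th percentile, within the random range) but -0.27 in the authors' values (0.70th percentile, below it), and the test as written named neither scale, while the main value alone met what the explanation needs; a stromal difference between the genotypes stays open too.

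The second pattern is the lower ratio of the brightest genes on the E14 array, where 10 of the 12 genes at least 2-fold lower were read as whole numbers in at least 1 channel. At the median channel ratio of 2.19, the knockout reading predicted from the wild-type reading exceeded the 16-bit limit for 8 of these 10 genes, and with the blank mean subtracted (ratio 2.55) for 10. The test asked for all of them, and the 2 ways of taking the ratio disagree. These counts also follow largely from the choice of genes. Whole-number wild-type readings started at 28390, and the lowest predicted knockout reading was 62144, already close to the limit. The counts therefore cannot decide on a ceiling of the Cy3 channel, which remains a candidate explanation. The knockout readings of these 10 genes ranged from 28002, for Mt2 with the lowest ratio, to 40499, below the 16-bit limit. The highest knockout reading was 41406 on this array and 62045 on the P1 array. The 10 genes hold Rpl41 and Ppia, which most cells express, beside liver genes, and a lower level of any of them in the knockout stays open.

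The third pattern is Supt16, higher on both arrays and a neighbour of Mmp14 on chromosome 14. Among the 20 largest same-direction changes, 2 genes lay within 10 Mb of Mmp14 in the main values, which are the targeted gene and Supt16 itself, so that count says nothing on a flanking segment carried with the allele. In the authors' values there were 3, with Pnp as well (chosen after its value was seen), which ranked 443rd in the main values and whose knockout signals of 89.0 and 88.1 lay just above the thresholds of 85.1 and 87.0. A flanking segment was therefore not decided. A dye effect of the probe also stays open: the correlation of 0.084 over all genes fell below the bound set for excluding it, but that bound was ill chosen, since a wide set of genes says little of 1 probe, and the dyes were never swapped.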

How the results depend on the processing

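The alternatives with the local background in normexp, the blank mean with loess, and without whole-number or lung genes were chosen after seeing the data. The cause of a change was not tested unless given. Mmp14 stayed lower in each alternative that gave it a value; it is too dim for the median-intensity filter. Of 940 list values, 785 kept their direction and their side of the random range.

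Local background subtracted: E14 823 higher, 309 lower, Mmp14 -1.95; P1 1116, 706 and -1.03; correlation 0.270, 265 shared genes; sterol synthesis 0.0039 on E14, and on P1 Aplnr 2.14 and Cldn5 3.12 turned positive. Normexp with local background: E14 169 higher, 5 lists, Mmp14 -0.45; P1 342 higher and -0.27; correlation 0.410, 82 shared genes; sterol synthesis 0.031 on E14, and on P1 growth hormone and IGF 0.017, Aplnr 0.12 and Cldn5 1.22.

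Offset 10: E14 7 higher, Mmp14 -1.69; P1 111 higher, 348 lower, Mmp14 -2.05. Median centring: E14 155 higher, 1 lower, Mmp14 -0.89; P1 274 and 117; correlation 0.377, 24 shared genes. The median of all genes was 0.29 on E14 and 0.05 on P1 there. A common shift of that size is enough to turn sterol synthesis (-0.11 to 0.50) and unfolded protein (-0.07 to 0.54) positive on E14, though not to reach these values. It does not by itself give the other changes of sign: on E14 megakaryocyte -0.14 and neutrophil -0.025, and on P1 cell cycle 0.026 and macrophage 0.014.

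The authors' values: E14 160 higher, 34 lower, Mmp14 -2.13; P1 403, 641 and -2.83; correlation 0.054, 11 shared genes. Blank mean and loess: E14 61, 133 and -2.11; P1 309, 655 and -2.72; 17 shared genes. Without whole-number readings: E14 2 lower, 2 shared genes, since those genes were removed.

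Threshold 1.5-fold: E14 39 higher, 28 lower; P1 362 and 524; 15 shared. Threshold 3-fold: E14 0 and 1; P1 12 and 55; 0 shared. Signal over background limits dim genes, whose ratios the offset shrinks.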

Other observations

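Both tests of dilution here were chosen after the results were seen. If lung RNA diluted liver RNA in the wild-type P1 pool, liver genes would be higher in the knockout by a common amount. The robust SD of the log2 ratios of hepatocyte maturation genes was 0.82 over 31 genes, against a bound of 0.44 from the spread between probes (0.65 over 28 genes without those read as whole numbers). Genes of 2 pools of separate animals can differ by more than probes do with or without dilution, so dilution was not decided for these genes. Erythroid markers had a median of -0.57, a value known when the test was written, and dilution of the wild type alone would not lower them.

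Liver stellate genes written down after the largest changes were seen had a median of 0.49 on the E14 array, with 10 of 10 members above 0, and -0.04 on the P1 array. The list holds Colec10, Colec11 and Lhx2, which are among the 12 highest E14 genes, and 7 of its 10 genes are in a list fixed beforehand, so the E14 value is not independent of the stellate list in the report. Liver sinusoidal genes, 7 of them in a list fixed beforehand, had medians of -0.04 and -0.18. On the P1 array the sinusoidal list lay at the 2.59th percentile (-0.35 and the 0.53rd in the authors' values), and the stellate list at the 25.7th (-0.14 and the 25.6th). Lung mesenchyme genes had a median of 0.14 on the E14 array and -0.36 on the P1 array, and lung-rich vessel and fibroblast genes 0.03 and -1.54, of which 10 are also in a list fixed beforehand. The seen lung epithelial list had medians of -0.01 and -3.83, and the unseen list -0.03 on the E14 array. The intestine list had a median of -0.03 on the E14 array and -0.02 on the P1 array, the kidney list -0.07 (0.28th percentile, and 25.4th in the authors' values) and -0.08, the stomach list -0.0042 and the adrenal list 0.01 on the E14 array; the skin list had too few members on both arrays, and the stomach and adrenal lists on the P1 array.

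The Y-linked gene Kdm5d, the single measured member of its list, had a log2 ratio of -0.36 on the E14 array and 0.37 on the P1 array, and -1.499 and 1.501 in the authors' deposited table. Its signals were 61.1 in the wild-type and 97.6 in the knockout channel of the E14 array, and 56.5 and 115 on the P1 array, near the thresholds.

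Unnamed probes changed as well. At least 2-fold differences were seen for 1 higher and 4 lower of 4482 unnamed probes detectable in both channels on the E14 array, and for 25 higher and 36 lower of 4478 on the P1 array.

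Of the lists fixed beforehand and not described above, all lay within the central 95 percent of random lists on both arrays in the main values. The medians on the E14 and P1 arrays were 0.01 and -0.02 for p53 response, -0.01 and 0.02 for Wnt targets, -0.02 and 0.03 for hypoxia and glycolysis, and -0.03 and 0.0021 for fatty acid oxidation. They were 0.01 and -0.06 for haematopoietic stem and progenitor markers, -0.01 and -0.01 for lymphocyte markers, 0.01 and 0.0049 for exocrine pancreas, 0.01 and -0.02 for muscle, and 0.01 and -0.01 for chromosomal neighbours of Mmp14. Among lists described above on the P1 array only, metalloproteinases had an E14 median of 0.04 (92.5th percentile, 99.4th in the authors' values). The TGF-beta list had an E14 median of 0.02 (68.3rd percentile, 99.0th in the authors' values).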
